A study of Caenorhabditis elegans with 4 samples.

How the data were processed

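Binding of LIN-13 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in C. elegans hermaphrodites at the second larval stage (L2). Per the labels, strain OP49 carries a transgene introduced by particle bombardment, in which lin-13 is fused to EGFP, together with unc-119 as the rescuing marker. Worms were grown at 20 degrees and crosslinked with 2% formaldehyde, and tagged complexes were collected with an antibody against GFP, per the labels' protocols. The series has 4 samples, namely 2 ChIP samples and 2 input samples of total chromatin, each kind numbered as replicates 1 and 2. The groups were taken from the sample titles. The description fields of the ChIP and input samples appeared exchanged, whereas titles, source names and the attached peak lists gave 1 assignment, which was used.

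The data analysed were 3 peak lists, 1 for each ChIP replicate and 1 combined list of the series. Peaks had been called with PeakSeq on genome build WormBase WS180, per the file headers and the caller named in the peak records. Each peak had a first and last base and a q-value computed by the authors, which PeakSeq derives by comparing ChIP with control reads. The aligner, the read filters, the q cut-off, the version of PeakSeq and the way the combined list was made are not given in the sources used here. No values of the input samples were analysed here, so no background level can be set beside the peaks. The lists hold no read counts, so the sequencing depth of each sample is unknown, and the number of peaks and their q-values depend on it.

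From the deposited q-values, −log10 q was computed as a strength per peak. It is the authors' value and ranks peaks within 1 list. Peaks of different lists were called shared where they overlapped by at least 1 bp, and a peak with several partners was paired with the one of largest overlap. Overlap expected by chance came from 1000 circular shifts of the peaks within each chromosome, with a one-sided p. Chromosome extents were taken as the last peak end in any list, 100.1 Mb in all, in place of the chromosome lengths of the build. Shares of peaks per chromosome were compared with these extents by two-sided exact binomial tests. The shares in the arms of the 5 autosomes, taken as the outer 25% at each end, were compared with 50% in the same way. Shares carry 95% Wilson intervals, which cover counting of peaks and not differences between worm cultures. Medians were compared by two-sided permutation tests with 100000 resamples, exact where a group held fewer than 10 values. Correlations across peaks used 100000 permutations, and shares among the best peaks were compared by Fisher's exact test. Families of tests were adjusted by the Benjamini-Hochberg method. Neighbouring peaks are not independent, so p-values for shares describe the lists and are too small where peaks cluster.

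The tests of replicate overlap, of correlation between replicate q-values and of support of the combined peaks were fixed before the data were examined. So were those of the X share and the autosome arms. The comparison of q between shared and unshared peaks was not among them. The shift test of the combined peaks is given as a chance level without a p, because the combined list was taken to rest on the same ChIP samples. Tests of the other chromosomes, of arms per chromosome, of the best peaks and of peak widths on X were chosen after seeing the data. Peaks were named by a rule fixed beforehand, namely the 20 combined peaks with the lowest q and up to 4 peaks with the lowest q in each replicate list that overlapped no peak of the other. Alternatives were a reciprocal overlap of 50%, midpoints within 200 bp, and the better-scored part of each list up to its median q. Others were equal numbers of best peaks, each replicate list alone, merging of overlapping or abutting peaks, and arms of 33.3% at each end. Added after seeing the data were joining of peaks closer than 5000 bp, peak width in place of q, one-to-one pairs, omission of the 2 farthest pairs, omission of chromosome I or V, and rescaling of q on chromosome I.

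Planned results on promoters, repeats, gene lists, motifs and the transgene genes were left out. They need a genome or annotation of build WS180, which was not used here, and coordinates were not converted between builds. Peaks are therefore named by position alone. The procedures were tested on simulated lists. A simulated list of 1482 peaks built to share 60.5% of them with another was recovered at 60.7%. Of 40 unrelated pairs, 0 had a shift p under 0.05, and of 100 uniformly placed lists, 6 had an X share with p under 0.05. Peaks were placed without clustering in all of these, and the unrelated pairs had a first list of 400 peaks and fewer shifts than the data. The simulations therefore do not show how the tests behave where peaks cluster. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.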

Results

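LIN-13 is a zinc-finger protein of the synMuv B class, a group of chromatin and transcription regulators that oppose Ras-driven vulval fates in C. elegans. Its binding was mapped in L2 hermaphrodites through a GFP-tagged transgene, to find the sites the protein occupies in the animal. The series has 2 ChIP samples and 2 input samples, and peak lists of ChIP replicate 1, ChIP replicate 2 and the combined data were analysed. All positions are in WormBase WS180. The labels do not say whether the 2 ChIP samples came from separate cultures, so differences between them may be technical.

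LIN-13::GFP peaks were found on all 6 chromosomes and were mostly narrow. Replicate 1 had 1494 peaks with a median width of 513.5 bp (quartiles 368 and 798.5 bp), and replicate 2 had 1997 peaks with a median of 506 bp (quartiles 364 and 781 bp). The combined list had 3503 peaks with a median of 514 bp (quartiles 365 and 801.5 bp), which covered 2.54 Mb or 2.54% of the analysed genome. In that list 163 peaks were wider than 2000 bp and 20 were wider than 5000 bp, while 53 were narrower than 100 bp. Depth was unknown, so the different peak numbers of the replicates cannot be set against it.

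The strongest combined peak was a domain of 15670 bp at II 10541880 to 10557549, with −log10 q of 285.7. It was followed by a domain of 10225 bp at V 6220778 to 6231002 (−log10 q 249.1) and by a peak of 2901 bp at X 16929137 to 16932037 (227.3). These were also the 3 strongest peaks of each replicate list. All 20 strongest combined peaks overlapped a peak in both replicates.

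Of these 20 peaks, 8 lay on X. Besides the one above they were X 14525329 to 14526417, X 8035745 to 8036954, X 2996408 to 2997666, X 11093665 to 11094499, X 4140729 to 4149004, X 4208520 to 4209835 and X 6295991 to 6297074, with −log10 q from 114.9 to 146.8. A further 6 lay on chromosome I, at 7656420 to 7661535, 9378285 to 9384306, 7079062 to 7086628, 5311319 to 5317053, 4171848 to 4172857 and 5372156 to 5378803, a share that did not differ detectably from that among the remaining peaks (adjusted Fisher's exact p = 0.33). Of the 20 strongest peaks of replicates 1 and 2, chromosome I held 2 and 1. In each list these included an interval near its right end that overlapped no combined peak. Only I 4171848 to 4172857 of the 6 was among them, at rank 15 in replicate 1. The weakest of the 6 in the replicates, I 5311319 to 5317053, ranked 190 in replicate 1 and 73 in replicate 2. The remaining peaks were V 723774 to 730607, III 3866738 to 3867872, III 13066745 to 13071937 and IV 8430666 to 8433412. The 8 X peaks spanned 835 to 8276 bp (median 1234.5 bp) and the 12 autosomal peaks 1010 to 15670 bp (median 5878.5 bp), of which 9 exceeded 5000 bp. The exact permutation test of these widths, chosen after seeing them, gave p = 0.05, and among the best 100 combined peaks the difference between the medians of 1149.5 bp on X and 2257.5 bp on autosomes did not pass (adjusted permutation p = 0.35).

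**Figure D1:**
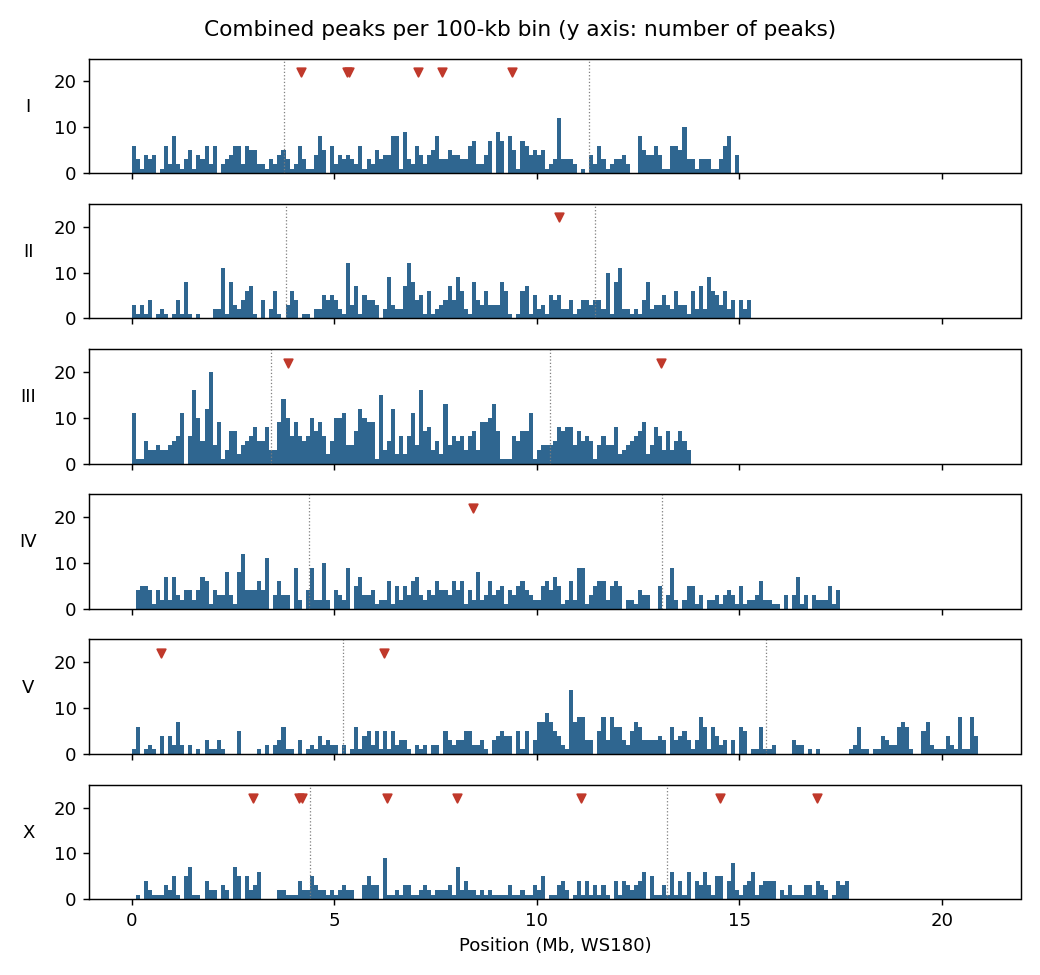
Number of combined LIN-13::GFP peaks per 100-kb bin (bars) along each chromosome in Mb of WS180. Triangles mark the 20 peaks with the lowest q, 8 of them on X, and dotted lines mark the borders of the arms, the outer 25% at each end.

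The replicates were compared to find how far their peaks coincided. In replicate 1, 1295 of 1494 peaks (86.7%, Wilson interval 84.9 to 88.3%) overlapped a peak of replicate 2, against 2.99% by chance. In replicate 2, 1287 of 1997 peaks (64.4%, 62.3 to 66.5%) overlapped a peak of replicate 1, against 2.25% by chance. Both circular-shift permutation tests gave p = 0.001, the smallest that 1000 shifts can give. The 2 shares differ partly because replicate 2 has more peaks. With equal numbers of best peaks from each list, they were 77.9% for replicate 1 and 77.2% for replicate 2. Overlap was near complete among strong peaks and lower among weak ones. The best 100 peaks of each replicate were all found in the other. With each list split by q into 4 parts of about equal number, from the strongest to the weakest, the shared part was 99.7, 97.1, 81.5 and 68.4% of replicate 1 peaks and 98.8, 83.8, 48.9 and 26.4% of replicate 2 peaks.

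Peaks strong in 1 replicate were strong in the other. Across the 1295 pairs of overlapping peaks, −log10 q had Spearman's rho of 0.76 and Pearson's r of 0.89 (permutation p = 1e-05 for each, the smallest possible). Without the 2 pairs farthest from the median of replicate 1, r was 0.88. These correlations are across peaks, which are not independent replicates. Some wide replicate 2 peaks held several replicate 1 peaks, and in the 1275 one-to-one pairs rho was 0.78 and r 0.95. The value of replicate 2 was the higher one in 962 pairs (74.3%), with a median ratio of 1.21, and in 73.9% of the one-to-one pairs. Because q depends on the unknown depth, these higher values do not show stronger binding in replicate 2. Peaks shared by the replicates had a higher median −log10 q than unshared ones, at 6.96 against 4.49 in replicate 1 and 8.77 against 4.72 in replicate 2 (permutation p = 1e-05, the smallest possible).

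**Figure D2:**
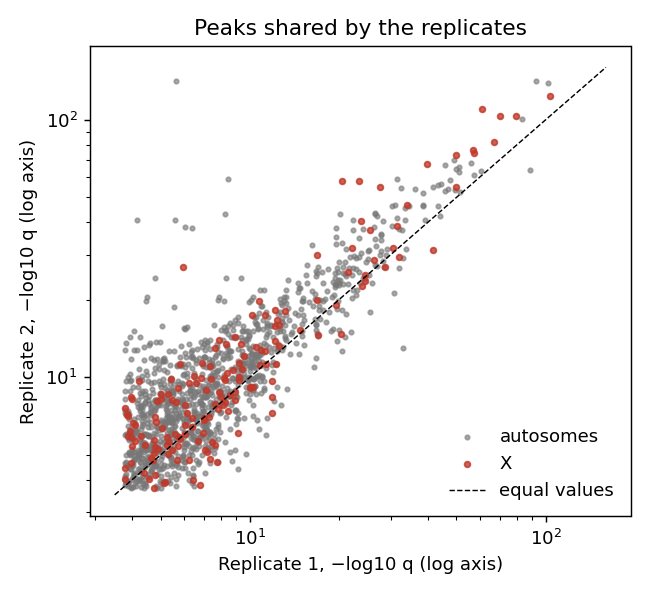
Authors' −log10 q in replicate 1 and replicate 2 for the 1295 pairs of overlapping peaks, on log axes, with X peaks in red, autosomal peaks in grey and a dashed line of equal values. In 74.3% of pairs the replicate 2 value is higher, and points far above the line include weak replicate 1 peaks paired with a wide replicate 2 peak.

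The strongest peaks of 1 replicate with no partner in the other were of moderate strength. In replicate 1 they were III 1516413 to 1517036 (−log10 q 10.9, rank 305), III 2100806 to 2101336 (9.41), X 768025 to 768515 (8.26) and X 14813305 to 14813641 (8.21). In replicate 2 they were III 10810863 to 10812403 (−log10 q 12.9, rank 357), V 6277079 to 6278527 (12.4), IV 5753231 to 5754704 (12.4) and II 2970497 to 2972315 (11.9). All 8 overlapped a peak of the combined list.

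The combined list was compared with the replicates to see which of its peaks were also called in a single sample. Of its 3503 peaks, 1250 (35.7%, Wilson interval 34.1 to 37.3%) overlapped peaks of both replicates, against 1.90% under random shifts. The combined list was taken to rest on the same ChIP samples, so overlap above this level, and lower q for peaks found in both, were built in and no test is given. A further 639 (18.2%) overlapped replicate 2 alone and 181 (5.17%) replicate 1 alone. The other 1433 (40.9%, 39.3 to 42.5%) overlapped neither. Peaks found in both had a median −log10 q of 15.97 and a median width of 690 bp, against 4.57 and 415 bp for those in neither. The share found in both was 100% in the strongest 10% of the list and 0.28% in the weakest 10%, where 90.9% overlapped neither.

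**Figure D3:**
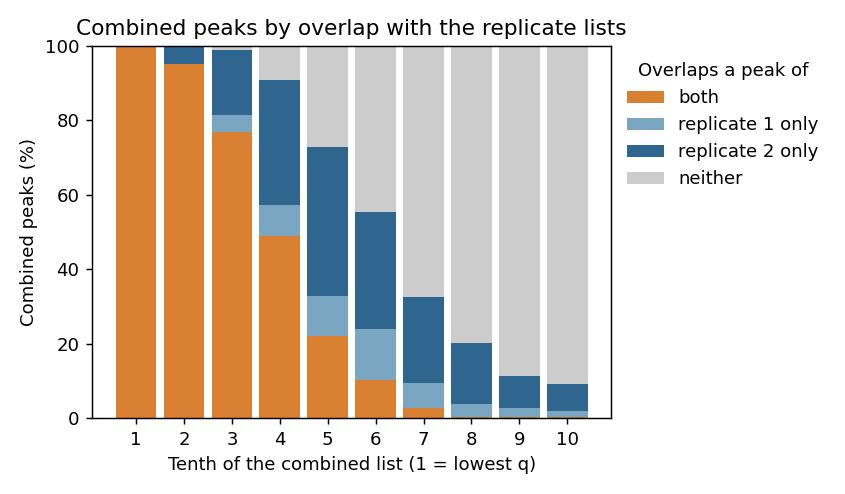
Share of combined peaks (%) that overlap a peak of both replicates, of 1 alone or of neither, in 10 parts of the combined list from the lowest q (1) to the highest (10). All peaks of the strongest part are found in both replicates and 90.9% of the weakest in neither.

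Peaks were unevenly spread over the chromosomes. Chromosome III was the densest, with 842 combined peaks or 61.1 per Mb, against 35.0 over all chromosomes. It held 24.0% of the peaks on 13.8% of the analysed length (exact binomial test, adjusted p = 1.4e-58), and 26.4% and 24.9% in replicates 1 and 2. Chromosome X, the planned test, held 410 combined peaks or 23.3 per Mb, which was 11.7% of peaks on 17.6% of the length (exact binomial test, adjusted p = 1.2e-21). Its share was 12.8% in replicate 1 and 11.7% in replicate 2. Chromosome V held 15.7% of combined peaks on 20.9% of the length, or 26.3 per Mb (exact binomial test, adjusted p = 1.8e-14).

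Chromosomes I, II and IV had 36.4, 34.8 and 35.6 combined peaks per Mb, and their shares did not pass the test against their lengths (exact binomial tests, adjusted p = 0.5, 0.91 and 0.77). Chromosome I held 15.6% of the peaks in the combined list, and 11.7% in replicate 1 (exact binomial test, adjusted p = 0.00033) and 12.6% in replicate 2 (adjusted p = 0.0026). Both replicate shares lay below its 15.1% of the length. Chromosome IV was above its 17.5% of the length in replicate 2, at 19.6% (exact binomial test, adjusted p = 0.013), but did not pass in replicate 1, at 18.01% (adjusted p = 0.7).

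**Figure D4:**
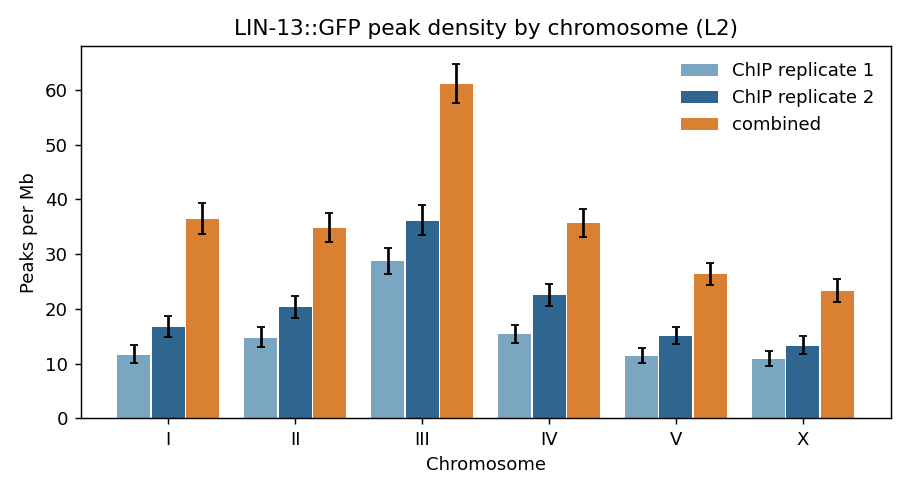
LIN-13::GFP peaks per Mb on each chromosome in the 3 lists, with Wilson 95% intervals over peaks as error bars. Chromosome III is the densest in each list, at 61.1 peaks per Mb in the combined one.

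In peaks found in all 3 lists, the combined −log10 q was a median of 2.37 times (bootstrap interval 2.26 to 2.49) the mean replicate value on chromosome I. On the other chromosomes together it was 1.87 times (permutation p = 1e-05, the smallest possible). Chromosome I was singled out after its share of the combined peaks was seen, and this p was not adjusted. The test shuffles single peaks and does not measure the spread between chromosomes.

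**Figure D5:**
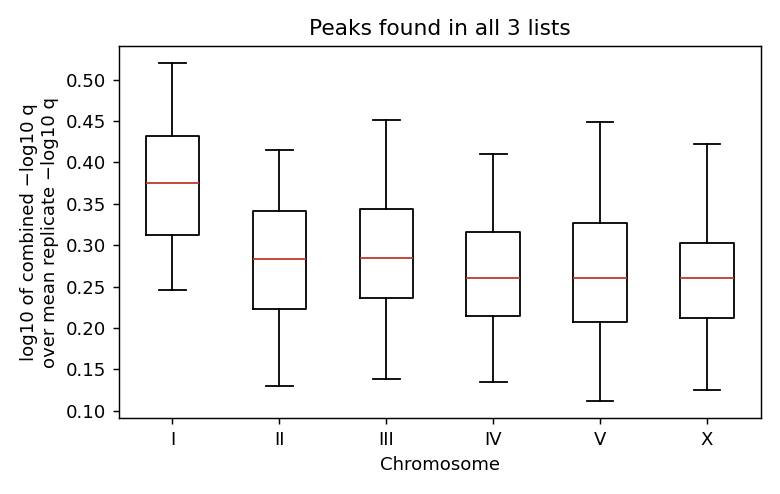
Log10 of the combined −log10 q over the mean replicate −log10 q, by chromosome, for the 1250 combined peaks found in both replicates (boxes, quartiles with the median in red; whiskers, 5th to 95th percentile). The median ratio was 2.37 on chromosome I and 1.82 to 1.93 on the other chromosomes.

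Over all peaks, those on X were fewer but wider, and many of the strongest peaks were on X. The median width of all X peaks was 660 bp against 495 bp on autosomes in the combined list. It was 660 against 491 bp in replicate 1 and 643 against 491 bp in replicate 2 (adjusted permutation p = 2e-05 for each list). The strongest X peaks were not wider. Among the best 100, the X median was 967 bp against 1128 bp in replicate 1 and 860.5 against 1091.5 bp in replicate 2. Neither difference passed (adjusted permutation p = 0.52 and 0.43), nor did that of the combined list given above. Of the best 20 peaks, 8 were on X in the combined list (40%, Wilson interval 21.9 to 61.3%, adjusted Fisher's exact p = 0.014) and 9 in each replicate (45%, adjusted Fisher's exact p = 0.0081). Of the best 50, X held 28% in the combined list and 26% in each replicate (Fisher's exact test, adjusted p = 0.014, 0.048 and 0.035). Of the best 100 it held 20% in the combined list, which did not pass (Fisher's exact test, adjusted p = 0.074), and 24% and 22% in the replicates (adjusted p = 0.014 and 0.017). Among the best 500 combined peaks the share was 11.8%. Set against the 17.6% of the length that X makes up, the Wilson intervals of the best 20 lay above it in each list. Those of the best 50 and the best 100 included it in each list. The family held 45 tests.

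Pooled over the 5 autosomes, peaks lay more often in chromosome centres than in arms, the outer 25% at each end, and chromosome V was the one autosome of the combined list to pass alone. In the combined list 1363 of 3093 autosomal peaks (44.1%, Wilson interval 42.3 to 45.8%) lay in arms, against 50% of the length (exact binomial test, adjusted p = 4.4e-11). The share was 46.6% in replicate 1 and 43.8% in replicate 2 (exact binomial test, adjusted p = 0.015 and 2.6e-07). Chromosome V had the lowest share in arms, with 186 of 550 combined peaks (33.8%, exact binomial test, adjusted p = 1.6e-13). It differed from the other autosomes together (46.3%, Fisher's exact p = 8.1e-08). That comparison was chosen because V had the lowest share, and its p was not adjusted. Chromosomes I, II, III and IV had 46.9, 46.3, 45.8 and 46.3% in arms and did not pass singly (exact binomial tests, adjusted p = 0.19, 0.15, 0.052 and 0.14). In replicate 2 chromosome III passed as well, with 44.5% in arms (exact binomial test, adjusted p = 0.046), whereas in replicate 1 it had 50.9% (adjusted p = 0.79). Without chromosome V the combined share still lay below 50% (exact binomial p = 0.00019), as did that of replicate 2 (45.7%, p = 0.0011), whereas that of replicate 1 was 49.0% (p = 0.52). On X, 52.9% of combined peaks lay in arms (exact binomial test, adjusted p = 0.26).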

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

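Over 14 results and 54 alternatives, 47 counted as unchanged. For tested results this meant the same direction and side of the threshold, whereas peak numbers and widths have neither. The count includes merging of overlapping or abutting peaks, which could change nothing because no list held such peaks. The alternatives on chromosomes III and I, one-to-one pairs, peak width, omitted pairs, joined peaks and omitted chromosomes were chosen after seeing the data. Shared peaks ranged from 75.4 to 88.0% of replicate 1 and from 56.4 to 77.2% of replicate 2, and combined peaks found in both from 28.2 to 36.6%. Against 1 replicate alone, 53.9% (replicate 2) or 40.9% (replicate 1) of combined peaks were found. Spearman's rho ranged from 0.75 to 0.81, the chromosome III share from 21.7 to 26.4%, the X share from 11.6 to 13.4% (13.9% against a length share of 20.7% without chromosome I) and the arm share from 43.8 to 46.6%, with 59.9% in arms of 33.3% at each end against 66.7% of the length. Keeping peaks up to the median q left 748, 999 and 1752 peaks by construction. Their median widths were 625.5, 633 and 658.5 bp, against 513.5, 506 and 514 bp for all peaks, a shift that was still counted as unchanged. The chromosome I share of the combined list was 15.6% (exact binomial p = 0.33). It turned below the length share of 15.1% in combined peaks found in both replicates (12.2%, exact binomial p = 0.0039). The lists of replicates 1 and 2 themselves were below it too (11.7 and 12.6%, exact binomial p = 0.00022 and 0.0017). For chromosome and arm shares, leaving a replicate out meant using the list of the other, and no combined list was called anew. With its q scaled back the chromosome I share was 13.01% (exact binomial p = 0.00078), where a factor taken from these same peaks lowers the share by construction. That scaling leaves 2 of the 20 strongest combined peaks on I and 9 on X. The cause was not tested by these alternatives. Other settings planned for promoters, repeats, gene lists and motifs were not run, because no annotation of the build was used. No paired analysis was possible because no values of the input samples were analysed. Unknown depth limits any reading of peak numbers.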

Other observations

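The tests on chromosome III, on X in each replicate, of peaks found in the combined list alone, and with reciprocal overlap were chosen after seeing the data. Peaks clustered in places. The densest 100-kb bin was III 1900001 to 2000000, with 20 combined peaks, 18 in replicate 1 and 15 in replicate 2. It was followed by the bins that start at III 1500001 and III 7100001 with 16 peaks each, and at III 6100001 with 15. Of 1003 bins, 33 held 10 or more combined peaks, 22 of them on chromosome III, the median bin held 3 and 109 (10.9%) held 0. Outside chromosome III, the densest bin started at V 10800001, with 14 peaks.

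A strong interval near the right end of chromosome I was in both replicate lists and overlapped no peak of the combined list. It spanned I 15063999 to 15067643 in replicate 1 (−log10 q 88.95, rank 4) and I 15063998 to 15067642 in replicate 2 (−log10 q 63.7, rank 18), 3645 bp in each. It was singled out after its values were seen. Both edges fell within 1 bp of each other in 2 of the 1295 pairs, while the median difference between starts was 53 bp. The last combined peak on the chromosome ended at 14953538. In all, 11 replicate 1 and 57 replicate 2 peaks overlapped no combined peak, and the next strongest had −log10 q of 4.99 and 7.14. The ribosomal RNA gene repeats lie at the right end of chromosome I in C. elegans, and whether the interval lies in them was not determined.

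Chromosome III had the most peaks per Mb in every list. Extra copies of the transgene loci, lin-13 and unc-119, both genes of chromosome III, could add peaks in a few places. Without its 10 densest bins, which held 143 peaks, the chromosome still had 1.67 times (bootstrap interval 1.504 to 1.853) the peaks per bin of the other autosomes. With all bins the ratio was 1.86, so the excess was not confined to the densest bins. These bins were chosen by density and the transgene loci were not located, so peaks due to extra copies were not tested. Looser calling would add weak peaks, yet 31% of the 200 strongest combined peaks (Wilson interval 24.999 to 37.7%) lay on chromosome III, against 13.8% of the length, as did 30% of the best 100 (21.9 to 39.6%), whereas 10% of the best 20 (2.79 to 30.1%) and 20% of the best 50 (11.2 to 33.0%) had intervals that include 13.8%. A scaling that raised strong and weak peaks of the whole chromosome alike, and gene density, stay open and untested. No biological explanation was tested.

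Chromosome I gained more peaks than the others in the combined list, with 2.57 times its mean replicate number against 1.93 elsewhere, and 52.7% of its combined peaks overlapped neither replicate, against 38.7% (Fisher's exact p = 1.2e-09). Among 4 equal parts of the chromosome the lowest ratio was 2.41 and the highest 2.75, against 1.93 (bootstrap interval 1.86 to 2.00) for the other chromosomes. All 4 parts thus had values above that interval. No interval was computed for the parts themselves, so whether the added peaks formed a local block cannot be decided from these ratios. A different scaling of chromosome I in the combined run is a candidate explanation: in peaks of all 3 lists, the median log10 ratio of combined to mean replicate −log10 q was 0.10 higher there (bootstrap interval 0.08 to 0.12, 152 peaks against 1098), and 0.11 higher (0.09 to 0.13) under 50% reciprocal overlap. Whether the missing interval at its right end took part was not tested, nor was any biological explanation.

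Chromosome X held few peaks but many of the strongest. An origin in 1 replicate alone is argued against, since X held 26% of the best 50 peaks (Wilson interval 15.9 to 39.6%) in replicate 1, where it stood out least, against 12.8% of all peaks there. That interval includes 17.6%, the X share of the length, and only among the best 20 peaks did the interval lie above it. A different scaling of the whole of X cannot be told apart from its absence by the median −log10 q. That median was 6.91 on X and 6.96 on autosomes, a difference of -0.0502 (bootstrap interval −0.60 to 0.58), too wide to decide. In peaks of all 3 lists, the median ratio of combined to mean replicate −log10 q was 1.82 on X (bootstrap interval 1.78 to 1.88). It was also 1.82 on IV and on V. These values argue against a scaling of X in the combined run alone. A scaling shared by all 3 lists would not show in this ratio and stays open. A small set of strong X sites, which the data may reflect, stays open, since sequence and annotation were not used here and no biological explanation was tested.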
